A study of Mus musculus with 2 samples.

How the data were processed

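Single-cell transcriptomes were measured in dissociated peripheral retina of mice at postnatal day 8, with 1 library per genotype. Per the labels' protocols, the area that expresses the alpha-Cre driver was dissected, digested with papain, strained and prepared with a droplet-based 3′ kit in which each captured transcript carries a unique molecular identifier (UMI). The group called DKO lacks Rb in the Cre area and p107 throughout, and the labels describe it as tumor-prone. The group called DKO_Skp2het has the same genotype plus 1 lost copy of Skp2, and the labels describe it as tumor-resistant. Each library's group was taken from its genotype label.

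The deposited values are raw UMI counts per gene and barcode, and the submitters' processing notes name Cell Ranger 2.2.0 and the mm10 build. The barcode filter used by the authors and the number of animals pooled per library are not given in the sources used here. Both libraries list 27998 gene identifiers. Of these, 27645 matched GENCODE release 21 of the mouse annotation, whose GRCm38 assembly is the one mm10 names, and coordinates were taken from that annotation.

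Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which removed 1 DKO and 2 DKO_Skp2het barcodes. Doublets were scored per library as in Scrublet, with 2 simulated doublets per cell, and the highest scores were removed at 0.8% for each 1000 barcodes, 105 in DKO and 216 in DKO_Skp2het. Scrublet's automatic threshold, run through scanpy 1.11.5, marked 1 and 6 barcodes and was treated as not having worked. The kept cells were 3515 in DKO and 4978 in DKO_Skp2het. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes without the cell cycle lists gave 30 principal components. Cells were joined to their 15 nearest neighbours and clustered with leidenalg 0.10.2 at resolution 1.0, both libraries together and without integration. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.

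Clusters were named "X-like" from fixed marker lists for 17 cell types. The thresholds for a name were set after the data had been seen: a mean log2 fold of the type's markers of at least 1.0 over all other cells, at least 3 markers above 2-fold, and no other type with as many markers among the 10 leading genes. The rule for comparing sizes was also set after the data had been seen. A class was compared in size only where at most 1 of its 10 leading genes differed by more than 1.5-fold between the libraries beyond counting error.

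Cells were called dividing when, after random thinning of every cell to 1500 UMIs, they held 3 or more UMIs of a core proliferation list of 26 genes. No kept cell was shallower than 1500 UMIs. Within dividing cells, UMIs of S phase genes were divided by UMIs of G2M genes, both lists taken without core proliferation genes. For gene comparisons, counts were summed over the cells of a library and population and given as CPM of the population's total. The log2 difference is that of CPM plus a pseudocount of 5, in DKO_Skp2het minus DKO, which understates differences of low genes.

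Genes were named by a fixed rule. It takes Skp2, Rb1, Rbl1, Rbl2, Cdkn1a, Cdkn1b and Cdkn1c, and the 5 genes per direction with the largest log2 difference in each class with at least 100 cells per library (10 per direction in dividing and amacrine-like cells) among genes with at least 100 UMIs. Genes without a proper name, genes that lead the class and markers of other classes were left out of the text. For each gene list described, members with the largest differences are named. Some results for single genes are not reported here. The 22 gene lists were fixed too, and a list's median over members with at least 50 UMIs is given with its percentile among 10000 random lists matched on expression. Lists within a class are described only below the 1st or above the 99th percentile, a limit set after the data had been seen. Exceptions, set beside their values over all cells, are amacrine transcription factors in amacrine-like cells, glial reactivity genes in Müller glia-like cells and ribosomal protein genes in rod-like cells. These were also chosen after the data had been seen. Unless stated otherwise, these rules and the alternatives were fixed before the data were examined.

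With 1 library per genotype no test was made, and no p-value or count of changed genes is given. Counts and CPM ratios carry exact 95% Poisson-based intervals, shares carry exact Clopper-Pearson intervals, and list medians carry intervals from 1000 Poisson draws of their members. All cover counting error only, and those of UMI sums and ratios treat UMIs of 1 cell as independent. Where a gene had 0 counts in 1 library, the fold is a bound against 3 counts over that library's cells of the population.

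Alternatives covered the gene and mitochondrial filters, doublet removal, clustering resolution, cell cycle genes in clustering, centring per library, thinning depth, the limit for a dividing cell, the lists behind the phase ratio, CPM scaling, the pseudocount and the minimum counts of a list member. A common UMI floor for both libraries and naming without the mean fold limit were chosen after seeing the data. The counting steps were tested on simulated data for the comparison of all kept cells. Of 50 genes per size among 11168, all were recovered with the right sign at 1.5-fold higher or lower and at 2-fold higher or lower. Intervals held the true value for 95.7% of the 10968 genes left at the same level, and for 88% to 98% of the genes per fold size. The simulated counts came from the Poisson model that the intervals assume, without cells. This therefore checks the computation only, not whether the intervals cover the spread between cells. Lists of 26 randomly chosen genes lowered 1.15-fold fell below the 1st percentile in 100% of 100 trials, and 2% of lists left alone passed a limit. Their members were simulated independently, so lists whose genes vary together were not checked. When DKO cells were split at random and 1 part was read at 0.781 of its depth, the median ratio of dividing shares over 20 splits was 1.00 (0.964 to 1.06) with thinning and 0.956 without. Both parts came from the same library, so this checks thinning against read depth only. It does not check the effect of the different UMI floors of the libraries.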

Results

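The data set holds 2 droplet-based single-cell libraries of mouse peripheral retina at postnatal day 8, 1 from Rb/p107 double-mutant retina (DKO) and 1 from the same genotype with 1 copy of Skp2 lost (DKO_Skp2het). Rb and p107 are pocket proteins that restrain cell cycle entry, and Skp2 is the substrate receptor of a ubiquitin ligase that marks the inhibitor p27 (Cdkn1b) for degradation. The series title asks whether the duration of the cell cycle sets the capacity for transformation, and the comparison is between a tumor-prone and a tumor-resistant genotype. The DKO library held 3621 barcodes and 24413761 UMIs, with a median of 4939 and a minimum of 3420 UMIs per barcode. The DKO_Skp2het library held 5196 barcodes and 25766024 UMIs, with a median of 3874 and a minimum of 2387. Thus 1897 kept DKO_Skp2het cells (38.1%) lay below the lowest UMI count of the DKO library. There were no replicates, so no difference below has a replicate check, and intervals cover counting error only.

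Skp2 was lower in the Skp2 heterozygous library, at 56.8 CPM (1349 UMIs) against 80.7 CPM (1885 UMIs) over all kept cells, a ratio of 0.704 (95% interval 0.656 to 0.756). In dividing cells the ratio was 0.709 (0.653 to 0.770). Rb1, the gene deleted by Cre, stood at a ratio of 0.977 (0.864 to 1.10), and Rbl1, which encodes p107, at 0.991 (0.895 to 1.10). Rbl2, the remaining pocket protein gene, was higher at 1.32 (1.10 to 1.60). Among the Cip/Kip inhibitors, Cdkn1b had a ratio of 1.00 (0.939 to 1.07) and Cdkn1c (p57) was higher at 1.20 (1.16 to 1.24). Cdkn1a (p21) had a ratio of 0.934 (0.910 to 0.959) over all cells, and its log2 difference turned from -0.10 to 0.095 when every cell was thinned to the same depth. Skp2 (ENSMUSG00000054115) lies on chromosome 15 at 9111985 to 9155425 of GRCm38, Rb1 (ENSMUSG00000022105) on chromosome 14 at 73183673 to 73325822, and Rbl1 (ENSMUSG00000027641) on chromosome 2 at 157145893 to 157204534. A 3′ tag outside the deleted part of a gene checks nothing, so the Rb1 and Rbl1 values do not test those deletions.

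**Figure D1:**
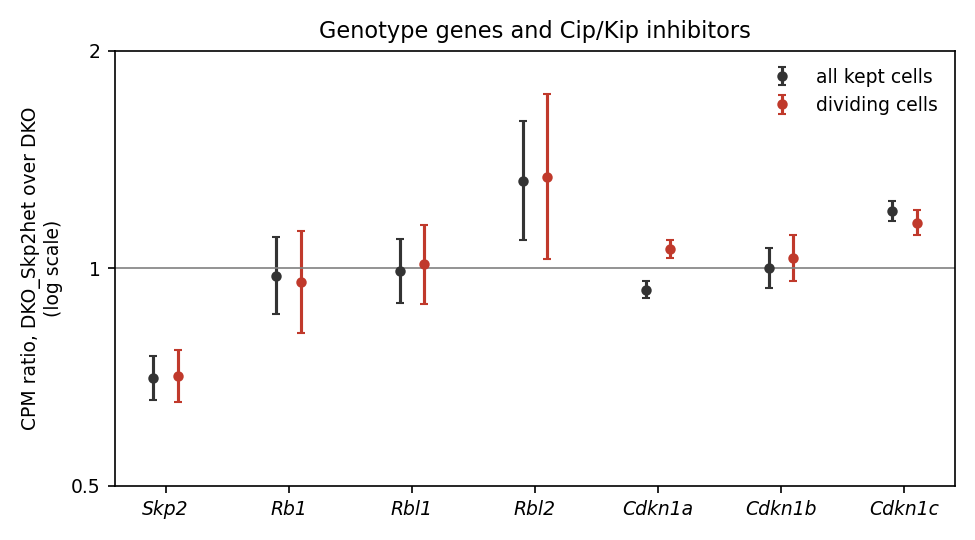
CPM ratio of DKO_Skp2het over DKO (log scale) for the genotype genes and the Cip/Kip inhibitors, in all kept cells and in dividing cells; points are ratios from 1 library per genotype and bars 95% counting intervals. Skp2 sits at 0.704 and 0.709, Rb1, Rbl1 and Cdkn1b span 1, and Rbl2 and Cdkn1c lie above 1.

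Photoreceptor, interneuron and glial classes were present in both libraries. Rod-like cells, marked by Nr2e3 and Sag, made up 4.44% of DKO cells (3.78 to 5.17) and 4.24% of DKO_Skp2het cells (3.70 to 4.84), a ratio of 0.955 (0.773 to 1.18). Müller glia-like cells, marked by Apoe and Rlbp1, made up 14.5% (13.4 to 15.7) and 15.8% (14.8 to 16.8), a ratio of 1.08 (0.969 to 1.21). Microglia-like cells made up 0.825% and 0.824%. Cone-, bipolar-, amacrine- and astrocyte-like cells were found too, but their sizes were not compared because genes that define them differed between the libraries. Clusters without a name held 70.3% of DKO and 70.6% of DKO_Skp2het cells, but their make-up differed. Among those compared in size, share ratios ran from 0.386 (0.307 to 0.483) in cluster 8 to 2.28 (1.89 to 2.77) in cluster 5. With both libraries held to the DKO minimum of 3420 UMIs, an alternative chosen after seeing the data, these were 0.583 and 1.40. Unnamed clusters nearest to Müller glia held 16.3% and 11.3%. The Müller glia-like ratio ran from 0.879 without the mean fold limit for a name to 1.47 at resolution 0.5, so its direction was not stable.

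A lower share of cells was dividing in the DKO_Skp2het library. With every cell thinned to 1500 UMIs, 61.8% of DKO cells (60.2 to 63.4) and 51.1% of DKO_Skp2het cells (49.7 to 52.5) carried 3 or more UMIs of core proliferation genes such as Mki67, the gene of the proliferation antigen Ki-67. The ratio was 0.828 (0.781 to 0.877). Rod-like cells showed 24.4% (17.9 to 31.9) against 10.9% (7.04 to 15.9), and Müller glia-like cells 48.9% (44.5 to 53.4) against 39.5% (36.1 to 43.0). Unnamed cluster 6, led by Igfbpl1 and Nhlh2, showed 27.7% (22.6 to 33.3) against 11.5% (8.12 to 15.6). Unnamed cluster 4 showed 73.3% and 73.2%, a ratio of 0.998, and unnamed cluster 2 44.6% and 30.1%, a ratio of 0.676 that was 1.03 at the common floor. Bipolar-like cells at 6.90% and 4.37%, amacrine-like cells at 4.65% and 3.42%, cluster 5 at 73.9% and 64.9% and cluster 7 at 8.90% and 4.13% overlapped within counting error. Unnamed clusters 1, 3 and 8 were dividing at 100% in both libraries. Core proliferation genes were among their leading genes (Birc5 in cluster 1, Ube2c in cluster 3, Hist1h2ap in cluster 8), so clustering had largely fixed these shares. Unnamed cluster 14 was at 100% too. Like cluster 1 it was nearest to Müller glia, so the Müller glia-like shares leave such dividing cells out. Microglia-like cells, used as background, showed 3.45% (1 of 29 cells, median depth 9600 UMIs) and 0 of 41 cells (0 to 8.60%, median depth 7519). Median depths of all kept cells were 4863 and 3799.5 UMIs, 476 and 835 cells lay at 2 or 3 UMIs, and unthinned shares were 80.1% and 69.1%. At the common floor of 3420 UMIs the ratio was 0.918 (0.862 to 0.978).

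**Figure D2:**
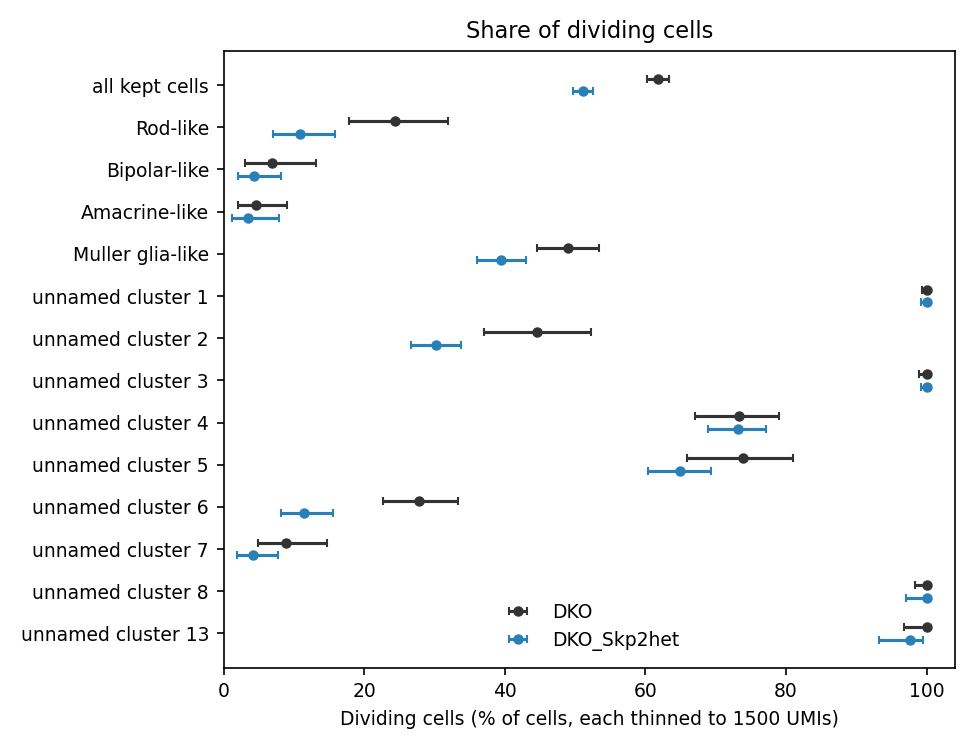
Share of dividing cells (% of cells thinned to 1500 UMIs) in DKO and DKO_Skp2het for all kept cells and for each class or unnamed cluster with at least 100 cells per library; points are shares in 1 library and bars exact 95% intervals. Rod-like cells stand at 24.4% and 10.9% and unnamed cluster 6 at 27.7% and 11.5%, while clusters 1, 3 and 8 are at 100% in both.

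Among dividing cells, transcripts of the S phase list, which holds no histone gene, were more abundant relative to those of the G2M list in the DKO_Skp2het library. UMIs of S phase genes, which serve DNA replication, stood at 0.360 of those of G2M genes in 2172 dividing DKO cells (0.354 to 0.367). In 2546 dividing DKO_Skp2het cells they stood at 0.407 (0.401 to 0.414), a ratio between libraries of 1.13 (1.10 to 1.16). These intervals, and those per cluster below, treat UMIs as independent, although UMIs of 1 cell share its phase. They therefore leave out the spread between cells. Over 10 thinning draws of the same cells the ratio ran from 1.126 to 1.163. Within clusters the ratio went both ways, with 0.871 (0.816 to 0.931) in cluster 3, 0.817 (0.713 to 0.937) in cluster 12, 1.14 (1.04 to 1.24) in cluster 8 and 1.04 (0.959 to 1.12) in Müller glia-like cells. At the common floor of 3420 UMIs the ratio over all dividing cells was 0.998 (0.972 to 1.03), so no difference was detectable there.

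Over all kept cells, the core proliferation and G2M lists were lower in DKO_Skp2het, and the S phase list was not. Of the 26 core proliferation genes 25 lay below 0, with a median log2 difference of -0.20 (percentile 0 of random lists). The histone gene Hist1h2ap had a ratio of 0.460 (0.443 to 0.478), Cdca3 0.758 (0.736 to 0.780) and Mki67 0.796 (0.767 to 0.825). The S phase list holds no histone gene, so the lower Hist1h2ap counts only in the core proliferation list. Of 54 G2M genes 51 lay below 0, with a median of -0.13 (percentile 0), but the median was 0.033 at the common floor. S phase genes had a median of 0.0091, 24 above and 21 below 0, and Cdca7 and the thymidylate synthase gene Tyms were higher at 1.21 (1.14 to 1.29) and 1.18 (1.14 to 1.23). The SCF-Skp2 ligase list had a median of -0.13 (5 of 7 below 0, percentile 1.82), with Skp1a at 0.885 (0.846 to 0.926). Cyclins and their kinases had a median of 0.11 (percentile 98.5), with the D-type cyclin gene Ccnd3 at 1.28 (1.174 to 1.398). The cyclin-dependent kinase inhibitor list (-0.025), E2F and pocket proteins (-0.025) and p53 targets (-0.0044) lay within the middle of random lists.

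Within dividing cells, genes of cyclins and of cell cycle inhibitors were mostly higher in DKO_Skp2het, to degrees that depended on depth. All 12 genes for cyclins and cyclin-dependent kinases lay above 0 in CPM of total UMIs, with a median log2 difference of 0.16 (percentile 99.8). With thinned counts the list's median was 0.038 (-0.047 to 0.12), and Ccnd2 (18 and 50 UMIs) turned to -0.17. Ccne1, whose product drives S phase entry, had a ratio of 1.32 (1.21 to 1.44). Of 8 cyclin-dependent kinase inhibitors 7 lay above 0, with a median of 0.12 (percentile 95.04). Cdkn2a, the gene of p16 and p19Arf, was at 1.52 (1.33 to 1.74) and Cdkn2c at 1.16 (1.12 to 1.21). Tyms was at 1.32 (1.26 to 1.38) and Hist1h2ap at 0.544 (0.523 to 0.565). Medians were 0.031 for core proliferation, 0.040 for S phase and 0.071 for G2M genes. The cells were chosen by core proliferation UMIs, and the core proliferation and G2M medians turned to -0.085 and -0.071 when counts were thinned. The S phase median was 0.12 with thinned counts. At the common floor the core proliferation and G2M medians rose instead, to 0.14 and 0.18. The direction of these 2 medians thus depended on how depth was handled. Median-of-ratios scaling, which moves all genes the same way, put core proliferation at -0.0018, S phase at 0.0065 and G2M at 0.039. Further medians were 0.0053 for the SCF-Skp2 list, 0.016 for E2F and pocket proteins, 0.068 for p53 targets and 0.092 for apoptosis genes.

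Summed over all dividing cells, photoreceptor and inhibitory neuron genes were lower in DKO_Skp2het, together with a different make-up of the dividing cells. The phototransduction list had a median log2 difference of -0.42 with 15 of 17 members below 0, which was -0.23 with doublets kept, -0.27 with thinned counts and -0.22 at a pseudocount of 20 CPM. Gngt1, a subunit of rod transducin, had a ratio of 0.638 (0.594 to 0.685) and the rod channel gene Cnga1 0.575 (0.459 to 0.717). Amacrine transcription factors had a median of -0.29 with 17 of 18 below 0, including Tfap2b at 0.427 (0.361 to 0.503) and Ebf1 at 0.518 (0.477 to 0.561). Inhibitory transmission genes had a median of -0.33 with 9 of 12 below 0, including the glycine receptor gene Glra2 at 0.448 (0.347 to 0.575) and the glycine transporter gene Slc6a9 at 0.538 (0.420 to 0.686). All 3 medians lay at percentile 0 of random lists. Of 2172 dividing DKO cells and 2546 dividing DKO_Skp2het cells, 38 and 23 were rod-like, 79 and 35 lay in unnamed cluster 6 and 147 and 63 in unnamed cluster 12. In the clusters with 100% dividing cells in both libraries, the 95% interval of the ratio of summed phototransduction CPM was 1.06 to 1.25 in cluster 1, 0.971 to 1.19 in cluster 3, 0.900 to 1.09 in cluster 8 and 1.05 to 1.60 in cluster 14, so none lay below 1. In cluster 13, with 100% and 97.6% dividing cells, the list was lower, at 0.650 (0.582 to 0.724). The neuronal transcription factor gene Nhlh2 was at 0.477 (0.438 to 0.518) and Cplx3, which encodes a complexin of ribbon synapses, at 0.499 (0.460 to 0.542). Among the other genes with the largest differences, Cwc22, a splicing factor gene, was higher at 4.20 (3.68 to 4.79), Igfbp7 at 4.47 (3.34 to 6.08) and Cd44 at 3.66 (2.68 to 5.07). Igfbp7 leads unnamed cluster 24, which is nearest to endothelial cells. Of that cluster, 1 of 4 DKO cells and 2 of 9 DKO_Skp2het cells were dividing. How much of the Igfbp7 difference came from these cells or their free RNA was not tested, so it may not hold for dividing cells in general. Plvap, an endothelial diaphragm gene, was lower at 0.215 (0.170 to 0.270), Klhl35 at 0.398 (0.335 to 0.471) and Pigz at 0.216 (0.141 to 0.321). Plvap UMIs did not come mainly from cluster 24, which held 1 and 1 of them, against 805 and 310 over all kept cells. Gpr137b-ps had 249 UMIs in DKO and 0 in DKO_Skp2het, at least 71.0-fold lower against a floor of 3 counts over all dividing cells of the library.

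Over all kept cells the neuronal lists went in different directions. Amacrine transcription factors were lower (median -0.22, 16 of 19 below 0, percentile 0), with Ptf1a, which specifies amacrine and horizontal cells, at 0.548 (0.473 to 0.633) and Tfap2b at 0.616 (0.578 to 0.657). Within amacrine-like cells the same list had a median of -0.038, with 4 members above and 5 below 0 (percentile 33.2). Inhibitory transmission genes were lower (median -0.093, percentile 0.58), with the GABA synthesis gene Gad1 at 0.556 (0.468 to 0.659). Bipolar synapse genes were higher (median 0.14, percentile 99.4), with Trpm1, the ON bipolar channel gene, at 2.09 (1.81 to 2.41) and Pcp2 at 1.68 (1.59 to 1.78). Phototransduction genes had a median of 0.036 (percentile 66.04). The retinoblastoma-associated list was lower (median -0.18, 9 of 10 below 0, percentile 0.04), with the oncogene Mycn at 0.775 (0.737 to 0.816) and Bcor at 0.806 (0.730 to 0.891). Sums over all cells also move with the share of each cell class. Ptf1a led unnamed cluster 12, which held 173 DKO and 78 DKO_Skp2het cells. That cluster was not compared in size because 4 of its leading genes differed between the libraries.

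**Figure D3:**
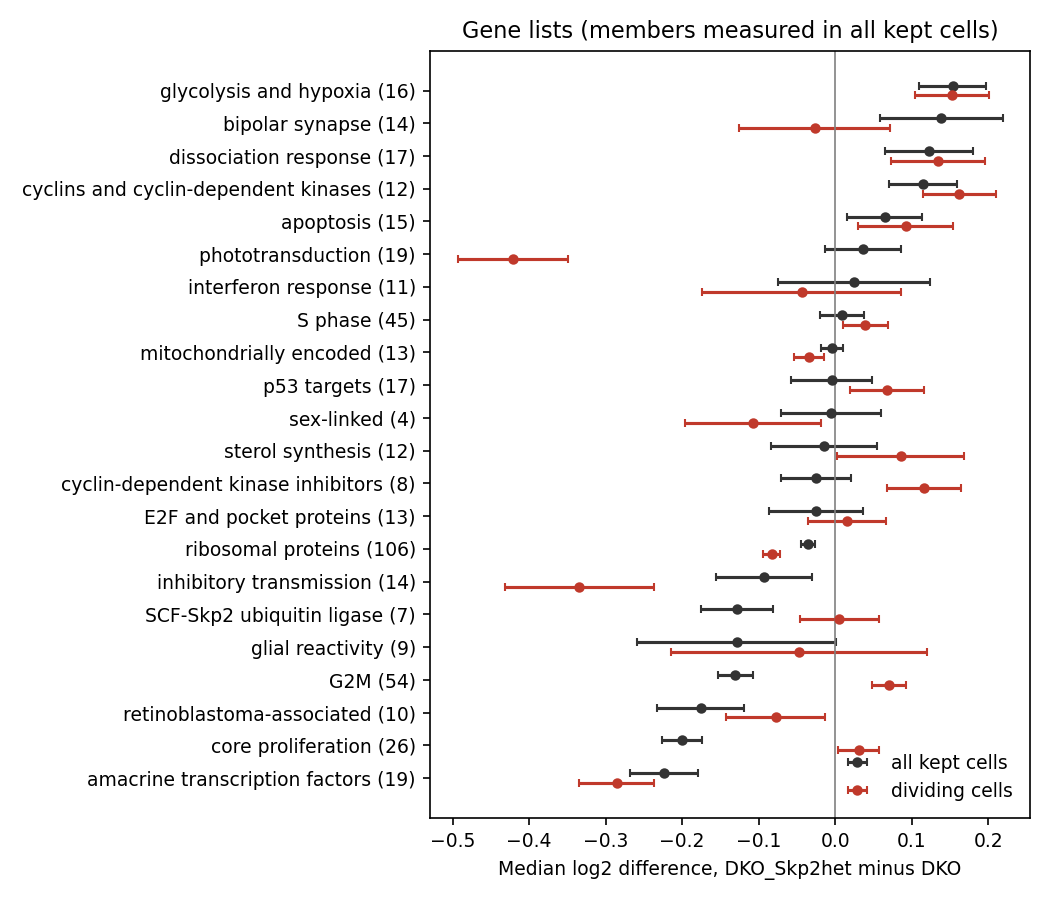
Median log2 difference (DKO_Skp2het minus DKO) of each gene list in all kept cells and in dividing cells, with the number of members measured in all kept cells in brackets; bars are 95% counting intervals of the median, with 1 library per genotype. Core proliferation and G2M genes stand at -0.20 and -0.13 in all cells and at 0.031 and 0.071 in dividing cells, where phototransduction genes stand at -0.42.

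Rod-like cells of the DKO_Skp2het library held fewer cell cycle transcripts, in both clusters that form the class. Cluster 11 (123 and 181 cells) had a ratio of summed core proliferation CPM of 0.372 (0.337 to 0.409), and cluster 18 (33 and 30 cells) of 0.705 (0.596 to 0.833). Over the class the sums were 1446 and 625 CPM, against 214 and 376 CPM in microglia-like cells, and RNA from outside the cell was not subtracted. Core proliferation genes had a median log2 difference of -1.26 (15 of 16 below 0), G2M genes -0.83 (24 of 25) and S phase genes -0.22 (29 of 36). The kinetochore gene Cenpf had a ratio of 0.259 (0.168 to 0.388), the mitotic ubiquitin enzyme gene Ube2c 0.301 (0.192 to 0.457) and the securin gene Pttg1 0.258 (0.154 to 0.414). All 5 measured cyclin-dependent kinase inhibitors were lower too (median -0.73), including Cdkn1b at 0.545 (0.374 to 0.785) and Cdkn2c at 0.459 (0.313 to 0.662). The retinoblastoma-associated list had a median of -0.29, with Mycn at 0.595 (0.451 to 0.780), and the dissociation response list -0.22. Phototransduction genes, several of which define the class, were higher (median 0.14, 13 of 18 above 0, percentile 99.7), with a median of 0.078 when doublets were kept and 0.23 with thinned counts, though Pde6a was lower at 0.663 (0.539 to 0.813). Pgm2 and Zmat5 were higher at 4.56 (2.84 to 7.62) and 2.96 (2.03 to 4.38). Zmat5 is not particular to rod-like cells, since it was higher in 15 of the 15 clusters with at least 15 UMIs of it. Rod-like cells were deeper in DKO, with a median of 6748 against 4471 UMIs.

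In bipolar-like cells, core proliferation genes summed to 807 CPM in DKO and 379 CPM in DKO_Skp2het, against 214 and 376 CPM in microglia-like cells. RNA from outside the cell was not separated from RNA made in it in either class. Core proliferation genes had a median log2 difference of -0.67 (6 of 6 below 0), G2M genes -0.38 (13 of 16) and S phase genes -0.31 (8 of 12). Sox11, a transcription factor gene of immature neurons, had a ratio of 0.378 (0.329 to 0.434), Nhlh2 0.343 (0.2501 to 0.466) and Hmgb2 0.472 (0.401 to 0.554). Amacrine transcription factors were lower (median -0.35), with Pax6 at 0.283 (0.197 to 0.399) and Ebf1 at 0.401 (0.310 to 0.514). Eef1a2 was higher at 2.28 (1.71 to 3.06) and Sulf2 at 1.99 (1.41 to 2.84). Bipolar synapse genes, several of which define the class, were higher (median 0.34, 11 of 13 above 0, percentile 100), though Scgn was lower at 0.480 (0.330 to 0.691). Phototransduction genes had a median of 0.66 (percentile 100), or 0.19 with thinned counts. Their sums were 616 and 961 CPM, below the level of microglia-like cells, a class that should lack them, in DKO (771 CPM) and above it in DKO_Skp2het (475 CPM). In microglia-like cells they were thus lower in DKO_Skp2het, with a ratio of 0.617 (0.496 to 0.764).

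In amacrine-like cells the cerebellin gene Cbln4 was higher in DKO_Skp2het at 3.97 (2.78 to 5.77), the granule protein gene Scg5 at 2.33 (1.86 to 2.92), the neuropeptide gene Vip at 2.37 (1.55 to 3.67) and the transcription factor gene Nr2f1 at 2.25 (1.54 to 3.33). Scg5 was higher in 15 of the 15 clusters with at least 15 UMIs of it, so it is not particular to this class. The lipoprotein lipase gene Lpl was lower at 0.285 (0.207 to 0.386), Cks2 at 0.429 (0.270 to 0.664), Lypd1 at 0.427 (0.261 to 0.678) and Spock1 at 0.473 (0.308 to 0.711). Cartpt and Sst, which are among the leading genes of this class, differed by more than 1.5-fold between the libraries. Over all kept cells Sst had 151 UMIs in DKO and 687 in DKO_Skp2het. A different mix of cells within the class was not separated from a change within its cells. Phototransduction genes had a median log2 difference of 1.59 (6 of 6 above 0), or 0.46 with doublets kept. Their sum in DKO, 620 CPM, was below the 771 CPM of microglia-like cells, while in DKO_Skp2het it was 996 CPM (928 to 1067) against 475 CPM (402 to 558).

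Müller glia-like cells of the DKO_Skp2het library had lower proliferation genes, with a median log2 difference of -0.28 for core proliferation (22 of 23 below 0) and -0.17 for G2M genes (33 of 42). Birc5, the survivin gene, had a ratio of 0.636 (0.478 to 0.844), Hist1h2ap 0.427 (0.320 to 0.565) and Ckap2l 0.551 (0.381 to 0.792). The class joins cluster 0 (473 and 706 cells), where the ratio of summed core proliferation CPM was 0.825 (0.795 to 0.857), and cluster 15 (38 and 79 cells), where it was 1.40 (1.08 to 1.84). The stress gene Nupr1 was lower at 0.213 (0.141 to 0.315), the imprinted RNA Meg3 at 0.417 (0.368 to 0.473) and Plvap at 0.149 (0.107 to 0.204). Lcn2, an acute-phase gene of reactive glia, had 198 UMIs in 10 of 511 DKO cells and 0 UMIs in 785 DKO_Skp2het cells, at least 93.2-fold lower against a floor of 3 counts over this class in the library. Cwc22 was higher at 5.92 (4.24 to 8.47), Creg2 at 5.01 (3.31 to 7.87) and the glutathione transferase gene Gsta4 at 2.51 (1.85 to 3.45). Neither Cwc22 nor Gsta4 is particular to this class. They were higher in 15 of 15 and 7 of 7 clusters with at least 15 UMIs of the gene. Creg2 was higher in 4 of 4 such clusters and Plvap lower in 11 of 13, so these 2 genes are not particular to the class either. The G2M median in this class was 0.17 at clustering resolution 0.5. Dividing cells of unnamed clusters 1 and 14, nearest to Müller glia, are not part of the class.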

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

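The common UMI floor and naming without the mean fold limit were chosen only after the results were seen. No paired analysis was possible because each genotype had 1 library. Results by cluster number used the cluster labels of the main analysis. They have no value at the other resolutions, with cell cycle genes in clustering or with centring per library. The Skp2 ratio kept its direction under all 9 alternatives (0.694 to 0.716). The dividing share stayed lower in DKO_Skp2het under all 16 (0.752 to 0.918), and the rod-like ratio ran from 0.941 to 1.05 over 13. Of 1337 gene values under alternatives 10 turned and a further 195 left the counting interval of the reported value. Of 642 list medians 6 turned and a further 102 left it. A value counted as turned only where the interval of the reported value excluded no difference and the sign changed. Other changes of sign are not in the counts of turned values. Single genes were run only with doublets kept, other CPM scalings, other pseudocounts, thinned counts and the common floor. Ratios in the next sentences are DKO_Skp2het over DKO, differences are log2, and the cause was not tested except where stated. Depth limits the lowest counts: folds of genes near 100 UMIs rest on wide intervals, and a dividing cell can be 1 UMI from the limit.

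With thinning to 1000 or 2500 UMIs the dividing ratio was 0.777 or 0.888, and with a limit of 5 UMIs it was 0.752. At the common floor it was 0.918, and 1.03 in unnamed cluster 2. The S to G2M ratio was 1.16 at a mitochondrial limit of 10%, 1.16 with doublets kept, 1.06 without thinning, 1.17 at a limit of 2 UMIs, 1.06 at a limit of 5, 1.16 with full lists and 0.998 at the common floor. The Müller glia-like ratio was 1.47 at resolution 0.5, 0.961 at resolution 2.0 and 0.879 without the mean fold limit. Over 10 thinning draws, the reported one among them, the dividing ratio ran from 0.811 to 0.834. The S to G2M ratio ran from 1.126 to 1.163, with the reported 1.130 near the low end.

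With doublets kept, Gfap in dividing cells was at -0.095 and the sterol synthesis list at -0.026. At resolution 0.5 the G2M list in Müller glia-like cells was at 0.17. With median-of-ratios scaling, dividing cells had core proliferation at -0.0018, S phase at 0.0065 and G2M at 0.039. With every cell thinned to 1500 UMIs, Cdkn1a over all cells was at 0.095, Ccnd2 at -0.090 and Eda2r at 0.054. In dividing cells thinning gave Aurka at -0.13, Ccnd2 at -0.17, Eda2r at 0.092, Bad at -0.0079 and Grm6 at 0.039, and in bipolar-like cells Top2a at 0.33. Thinned list medians in dividing cells were -0.085 for core proliferation, 0.12 for S phase, -0.071 for G2M, 0.038 for cyclins and their kinases and -0.065 for the SCF-Skp2 list. At the common floor the G2M list over all cells was at 0.033, and dividing cells had core proliferation at 0.14, G2M at 0.18, cyclins and their kinases at 0.24 and cyclin-dependent kinase inhibitors at 0.20.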

Other observations

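All tests of explanations in this part were chosen only after the results were seen. Genes of glycolysis and hypoxia were higher in the DKO_Skp2het library, with a median log2 difference of 0.15 both over all cells (12 of 16 above 0, percentile 99.95) and in dividing cells (percentile 99.9). The enolase gene Eno1 had a ratio of 1.43 (1.39 to 1.46) over all cells and Aldoc 1.24 (1.13 to 1.36). Immediate-early genes of the dissociation response were higher as well, with a median of 0.12 over all cells (14 of 17 above 0, percentile 99.7) and 0.13 in dividing cells, and Jun at 1.38 (1.35 to 1.42) and Nr4a1 at 1.44 (1.30 to 1.59). In rod-like cells that list was lower instead (median -0.22, 4 above and 9 below 0). Ribosomal protein genes were lower except in rod-like cells (median 0.016), with a median of -0.035 over all cells, -0.083 in dividing, -0.14 in amacrine-like, -0.12 in Müller glia-like and -0.043 in bipolar-like cells. Rps28 stood at 0.684 (0.675 to 0.694).

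Glial reactivity genes had a median of -0.13 over all cells (-0.26 to 0.0013, percentile 0.475), and the largest member difference came from few cells. In Müller glia-like cells the list's median was 0.15 (-0.055 to 0.36), with 3 members above and 2 below 0 (percentile 86.2). The list's median was thus not lower in the main glial class, where 5 members were measured against 9 over all cells. Its mean log2 difference was lower, at -0.70 there and -0.45 over all cells. Lcn2, with 198 and 0 UMIs in the class, is in that mean. Lcn2 had 1322 UMIs in 43 DKO cells, 1020 of them in 3 astrocyte-like cells, against 8 UMIs in DKO_Skp2het. Lists near 0 over all cells were apoptosis (0.065), interferon response (0.024), sterol synthesis (-0.015) and mitochondrially encoded genes (-0.0039), though mt-Nd3 alone stood at 0.671 (0.649 to 0.695). The sex-linked list had a median of -0.0058. Ddx3y, on the Y chromosome, had 1593 and 1665 UMIs, and Xist, the X inactivation RNA, 5 and 8 UMIs.

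The first pattern weighed is the lower share of dividing cells. A different UMI floor is not its whole source, since at equal floors the ratio was 0.918 (0.862 to 0.978), although at a floor of 5000 UMIs it was 0.945 (0.863 to 1.03) and the interval reached 1. Free RNA of cycling genes stays open, since classes with few dividing cells went both ways: the core proliferation CPM ratio was 1.76 (1.27 to 2.45) in microglia-like cells, which can divide themselves, 0.841 (0.736 to 0.960) in amacrine-like and 0.470 (0.409 to 0.539) in bipolar-like cells. The Skp2 genotype may contribute too, but with 1 library per genotype it cannot be told apart from a difference between mice or preparations.

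The second pattern is the higher S to G2M ratio in dividing DKO_Skp2het cells. It was 0.998 (0.972 to 1.03) at equal UMI floors, so the difference in floor is a candidate explanation. With 11 clusters given equal weight it was 0.993 (0.968 to 1.02). The clusters' own ratios ran from 0.0833 to 1.04, so they stand partly for phases and equal weights level the phases too. A different mix of clusters therefore cannot be told apart from a different phase make-up.

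The third pattern is a set of 40 genes with the largest differences over all cells among genes with at least 200 UMIs, chosen after their values were seen, such as Cwc22 with 429 and 2016 UMIs. A different mix of clusters is not the source for the set as a whole, since with equal cluster weights the median difference kept 0.920 of its size, and 25 of the 33 genes measured in 5 or more clusters went the same way in every one. DNA carried along with the Skp2 allele would place these genes near it, and 0 of the 40 lay within 20 Mb of Skp2. Random matched sets had a median of 0 as well, and their central 95% reached 1. The count therefore does not separate the set from chance, and shows only that none of the 40 lay in that window. Chromosome segments of different origin in the mice could give neighbouring genes: 9 of the 40 had another within 2 Mb, such as Ocel1 and Plvap on chromosome 8, against a median of 4 in random matched sets, whose central 95% reached 10, so chance stays open. The genotype effect itself stays open too, untested with 1 library per genotype.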
